A study of Homo sapiens with 3 samples.

How the data were processed

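The human 7SK RNA was probed in HEK293T cells, an embryonic kidney line, by RNP-MaP, which locates protein contacts on an RNA by mutational profiling. Per the labels' protocols, cells received 10 mM SDA, an NHS-diazirine that attaches to lysine side chains, or 0.5% DMSO as the control, for 10 min at 37 °C. They were then exposed on ice to 2 J/cm2 of 365 nm light, which joins the diazirine to nearby RNA. RNA was released with proteinase K and extracted, and cDNA was made with Superscript II under conditions in which the enzyme writes a mutation at an adduct. Libraries were amplified by PCR with primers specific for 7SK, per the labels. There were 2 SDA libraries and 1 control library, and nothing in the labels says whether the SDA libraries came from separate cultures.

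The authors deposited, for each SDA replicate, a table with 1 row per nucleotide of the RNA. Per the file headers, these tables hold counts of mutations, of reads covering each nucleotide (read depth), of the reads usable for mutation calling (effective depth) and of reads mapped off target, for a modified and an untreated library. The deposited mutation rate is a fraction and was checked to equal mutations over effective depth to within rounding. The modified columns were taken as the SDA library of the replicate that the table is named for. The untreated columns were identical in both tables and were taken as the only library without SDA. The authors also deposited, per replicate, a ratio of SDA rate to control rate, a Z-factor score built from both rates and their errors, a site call per nucleotide, and a threshold on the ratio for each base. In the deposited tables, each called site had a ratio over its base threshold and a Z-factor score above 0. The reverse did not hold for 2 nucleotides of replicate 1 and 1 of replicate 2, which met both and were not called, so the rule is known only in part. Aligner, mutation caller and genome build are not given in the sources used here, and positions are therefore counted along the RNA from its 5' end, with no genomic coordinates. The sequence in the tables has 332 nucleotides, the length that the RefSeq gene table of assembly GRCh38.p14 gives for RN7SK.

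Effective depth was 0 at 44 nucleotides, at and next to the ends of the RNA, leaving values between nucleotides 19 and 306. A nucleotide was kept with an effective depth of at least 1000 in each library and at least 1 mutation over the 3 libraries, which left 287 (60 A, 90 C, 78 G and 59 U), from 19 to 305. Median effective depth over these was 193833 and 215665 in SDA replicates 1 and 2 and 260201 in the control. A count of 0, read as up to 3 counts, would allow a rate of up to 0.00155%, 0.00139% and 0.00115% at those depths. Intervals given for the control are exact Clopper-Pearson intervals at 95%. The reads come from PCR without molecular identifiers, so intervals and floors cover counting error only.

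Counts were tested with edgeR 4.0.16 in R 4.3.3, by its quasi-likelihood test (glmQLFit, glmQLFTest, two-sided) with the log of effective depth as offset and Benjamini-Hochberg adjustment over nucleotides at 0.05. The fit has 1 residual degree of freedom per nucleotide, from the SDA pair, and takes the single control to vary as they do. Its spread was shared fully between nucleotides, with a common dispersion of 0.00178. In a further fit, the median log2 SDA/control ratio of all measured nucleotides of the same base was added to the offset of the SDA libraries; values from it, or from ratios with that median subtracted, are called centred. Log2 ratios outside edgeR used a pseudocount of 0.5 mutations. The p-values rest on a shared spread between the SDA libraries, which may be technical, and not on the spread of each single nucleotide. Each standard error (SE) of an edgeR ratio was computed as the absolute log2 ratio over the square root of the test's F statistic. It rests on the same shared spread. An exact permutation of the libraries, 2 against 1, cannot go below p = 0.333.

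Bases were compared by a permutation test over nucleotides (100000 resamples, each base against the other 3). The tested regions were 5 domains with rounded boundaries (SL1 from 1, SL2 from 110, SL3 from 200, a linker from 280, SL4 and tail from 300), nucleotides 24 to 87 of SL1, the GAUC motifs, and nucleotides unpaired in the minimum free energy structure of RNAfold 2.7.2. Each was set against the remaining nucleotides by an exact circular-shift permutation test along the RNA, two-sided, with adjustment over the 5 domains and over the 2 elements. The smallest p this test can give is 0.00348. Nucleotides of 1 RNA are neighbours and are not independent replicates. Both SDA libraries were set against the same control, so 1000 sets of unchanged libraries were simulated with the fitted dispersion, at the real depths and with the base medians kept. The SDA libraries were compared with each other by Fisher's exact test per nucleotide. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.

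Before the data were examined, the groups, tests, alternatives and the nucleotides to be named were fixed. The named nucleotides are the 20 with the highest mean centred log2 ratio past the threshold and positive in both SDA libraries, and the 5 lowest that were negative in both. They also include the highest nucleotide in each run of shared authors' sites no more than 3 nucleotides apart, uridines 30, 40, 41 and 63, the GAUC nucleotides, the 3 highest control rates, and up to 3 nucleotides past Fisher's test between SDA libraries. The alternatives were DESeq2 1.42.0, exact tests of each SDA library, the legacy option of edgeR, read depth as offset, stricter minimums, both ends left out, other centring, a pseudocount of 5, rate differences, shifted boundaries and leaving out each SDA library.

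The centred edgeR test was tested on simulated data with 60 of 287 nucleotides changed, 20 for each fold. At a dispersion of 0.003, it recovered 12 of 20 changed 1.5-fold and 20 of 20 changed 2-fold or 3-fold, with 3 of 227 unchanged nucleotides called. At a dispersion of 0.02, these numbers were 2, 12 and 20, with 8 unchanged nucleotides called. Those 8 made up a larger share of the calls than the threshold of 0.05. The control was simulated with the same dispersion as the SDA libraries, so a control that varies more is not covered. In 300 simulated profiles of 287 nucleotides, the circular-shift test of nucleotides 24 to 87 passed 0.05 in 5% with no shift and in 82.3% with a planted shift of 0.5. That shift is larger than each centred log2 difference found for the domains and elements. Smaller shifts and other regions were not simulated, so the power of those tests is not known. The study's DMS mapping was not analysed here.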

Results

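RNP-MaP was used to find protein-binding regions of 7SK, the small nuclear RNA that holds the elongation factor P-TEFb inactive together with HEXIM proteins, and to set them beside the study's chemical mapping. SDA links lysines near the RNA to nucleotides, and these adducts are read as mutations. The data were 2 SDA libraries and 1 DMSO control library from HEK293T cells. Over the 287 measured nucleotides, the libraries held 114634 and 123950 mutations in SDA replicates 1 and 2 and 132582 in the control. Read depth per nucleotide was 199461 to 224020, 212031 to 242233 and 257053 to 290163, in the same order.

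SDA raised the mutation rate over much of the RNA by a small factor. The median rate was 0.114% and 0.113% in the SDA libraries and 0.0834% in the control. The SDA median was thus 1.36 ± 0.0166 times that of the control (SD of the SDA pair, n = 2, without the control's own spread). Of the 287 nucleotides, 228 had a higher rate than the control in both SDA libraries and 23 a lower rate in both. The background was uneven: C273, U191 and U223 had the highest control rates. They were 1.17% (exact 95% interval 1.13% to 1.22%), 1.08% (1.04% to 1.12%) and 1.04% (1.00% to 1.08%), against 1.19% ± 0.0227, 0.940% ± 0.153 and 1.11% ± 0.0525 with SDA (SD, n = 2). With 1 control library, no test was made of the overall effect, and the ratio of mean rates was smaller, at 1.14. Neither ratio is that of a typical nucleotide: the median ratio per nucleotide was 1.40 for A, 1.12 for C, 1.10 for G and 1.11 for U.

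Adenosines had the largest relative increase. Their median rate ratio to the control was 1.40, against 1.12 for C, 1.10 for G and 1.11 for U. The mean log2 ratio was 0.50 for A and 0.25 for the other bases, a difference of 0.25 (permutation test over nucleotides, adjusted p = 8e-05). G lay 0.16 below the other bases on the log2 scale, at 0.19 against 0.35 (adjusted p = 0.00326), and C lay lower at 0.23 against 0.33 (adjusted p = 0.0463). U, at 0.36 against 0.29, did not pass (adjusted p = 0.184). As a difference of rates, the direction for A and G turned (-0.0564 and 0.0629 mutations per 10000 reads, adjusted p = 0.908 for both) and U was higher than the other bases by 1.71 (adjusted p = 0.00244). The call for C was lost without SDA replicate 1 (adjusted p = 0.0607).

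Set against the control alone, 85 nucleotides had a higher rate with SDA and 2, G151 and C304, a lower one (edgeR's quasi-likelihood test, adjusted p under the threshold of 0.05). The higher ones were 31 A, 26 U, 17 C and 11 G. DESeq2 called 27 higher and 0 lower, and edgeR with read depth as offset called 20 and 0. Of the unadjusted edgeR p-values, 112 lay under 0.05. Without SDA replicate 1, C304 did not pass (adjusted p = 0.095, Fisher's exact test of the remaining library). G151, which no part of the naming rule covers, was named after its value was seen.

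Measured against the typical nucleotide of the same base, 27 nucleotides were higher with SDA and 12 lower. The highest was G300, at the 5' side of SL4, the stem-loop that the protein LARP7 binds. Its rate was 0.201% ± 0.00659 (SD, n = 2) against 0.0418% in the control, and its centred log2 ratio was 2.13 (SE 0.16, edgeR adjusted p = 8.73e-30). Next came C75, U54, U57 and A56, all in the distal part of SL1, the stem-loop that HEXIM proteins bind. A56 rose from 0.0708% in the control to 0.273% ± 0.00679 (SD, n = 2), with a centred log2 ratio of 1.46 (SE 0.14, edgeR adjusted p = 5.26e-19). C75 rose from 0.0438% to 0.145% ± 0.00402 (SD, n = 2), with a centred log2 ratio of 1.57 (SE 0.18, edgeR adjusted p = 7.3e-14).

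**Figure D1:**
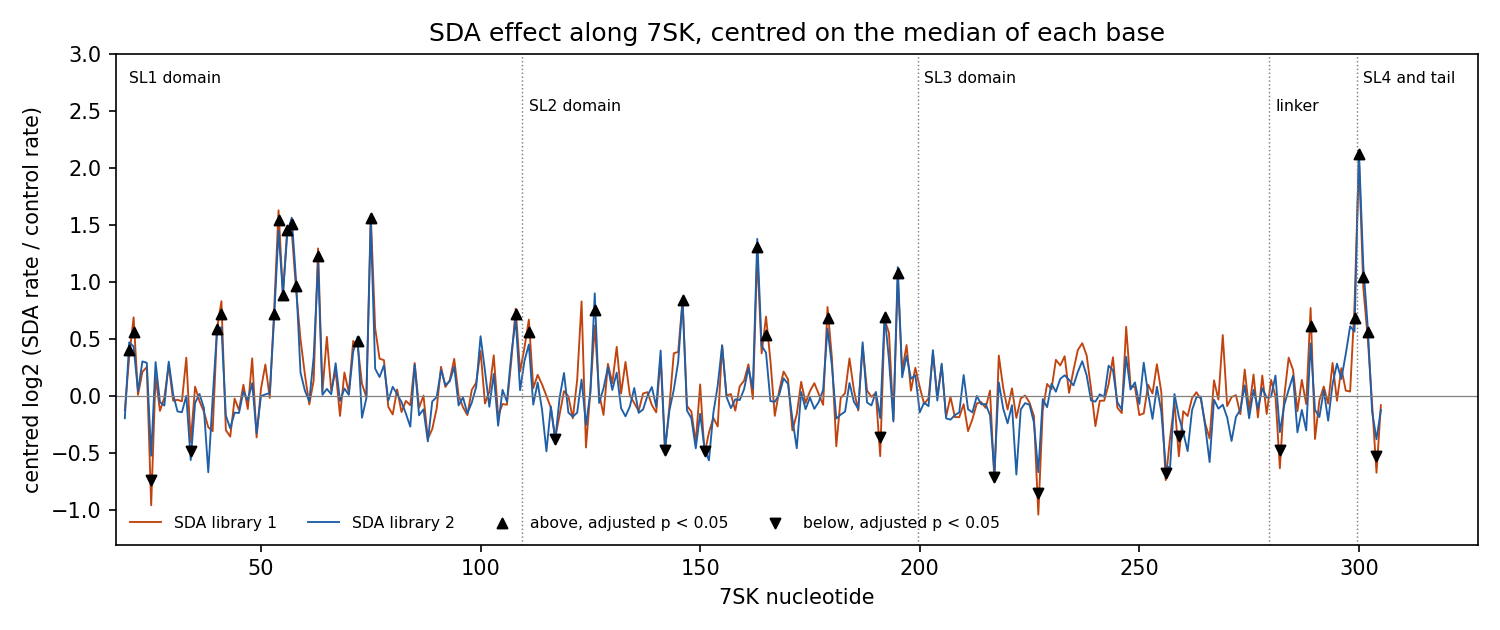
Log2 ratio of SDA to control mutation rate after subtraction of the median of the same base, for each SDA library, against the nucleotide of 7SK; triangles mark the mean at the 27 nucleotides above and 12 below the typical nucleotide of their base (edgeR adjusted p under 0.05), and dotted lines the domain boundaries. Means over 1 lie at U54, A56, U57, U63, C75, U163, C195, G300 and A301.

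U53, U54, G55, A56, U57 and U58 rose without a gap, with centred log2 ratios of 0.72, 1.55, 0.89, 1.46, 1.51 and 0.97. In the same arm lay U63 (1.23) and U41 (0.72). In SL2 the highest were U163 (1.32) and C195 (1.09), followed by A146 (0.84), A126 (0.78), A192 (0.70) and U179 (0.69). Toward the 3' end, U299 (0.68) and A301 (1.05) flanked G300, and C289 had a value of 0.62. C108, at the end of the SL1 domain, had a value of 0.72. Only U53, U54, A56, U57, U63, C75, A146, U163 and G300 also passed with both DESeq2 and read depth as offset, 9 of the 27. Of the others named here, U41, A126, A192, U299, C289 and C108 passed with neither, and G55, U58, C195, U179 and A301 passed with DESeq2 alone. The adjusted p-values of the 27 reached at most 0.0205, and their uncentred ratios to the control ran from 1.48 to 4.80.

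The lowest nucleotides were A227, A25, A217, A256 and C304. Their centred log2 ratios were -0.83, -0.72, -0.71, -0.67 and -0.51 (edgeR adjusted p at most 0.0145). Their rates were 0.777, 0.840, 0.859, 0.879 and 0.777 times the control, and C304 alone among them was also called lower without centring. DESeq2 called 15 nucleotides above and 2 below, and read depth as offset left 9 and 0. With the median of all nucleotides as centre, 39 were above and 10 below, and the calls of A25 and A256 were lost (edgeR adjusted p = 0.178 and 0.259). Exact tests of single libraries gave 37 above and 25 below without SDA replicate 1, and 49 and 21 without SDA replicate 2.

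**Figure D2:**
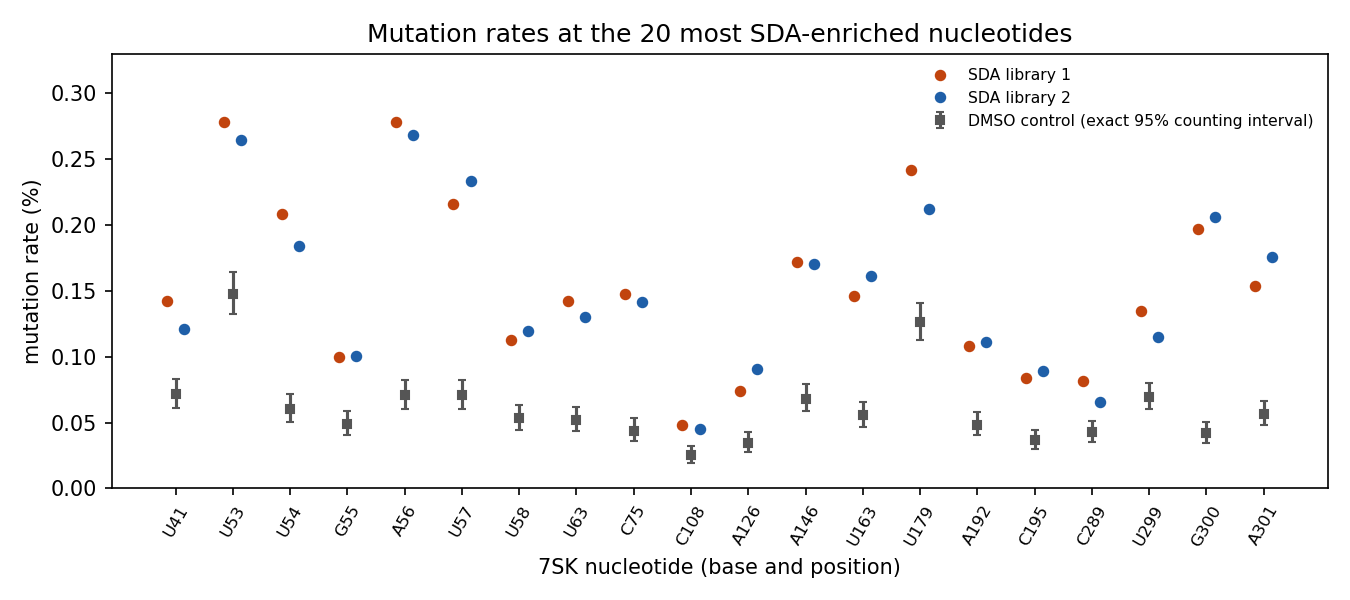
Mutation rate in percent at the 20 nucleotides with the highest mean centred log2 ratio, for each SDA library (circles) and the DMSO control (squares, with exact 95% counting intervals). Both SDA circles lie above the interval of the control at each nucleotide; at G300 the rates were 0.197% and 0.206% against 0.0418%.

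The SDA libraries ranked nucleotides alike. Across nucleotides, their log2 rates correlated with Pearson's r = 0.992 and Spearman's rho = 0.988, and each correlated with the control at r = 0.961 and 0.963. Their centred log2 ratios correlated with r = 0.897 and rho = 0.800. Because both ratios share the control, unchanged libraries simulated against it gave a mean r of 0.484 and at most 0.690. The covariance was 0.13 against 0.02 in the simulation, a difference of 0.11. The simulation already holds the shared control at the fitted dispersion. If the control varied more than that, part of the excess in r may still come from it, and as 1 library it could not be split. Nucleotides are not independent replicates. The libraries differed beyond sampling noise (chi-square 518 over 287 nucleotides). By Fisher's exact test, U191 and C295 differed between them: the rate in replicate 1 was 0.793 and 0.798 times that in replicate 2 (adjusted p = 3.8e-10 and 3.89e-07). U191 was also called below its base (centred log2 ratio -0.35, edgeR adjusted p = 0.000317), at -0.53 in replicate 1 and -0.19 in replicate 2. That call was lost with DESeq2 (adjusted p = 0.915) and with read depth as offset (edgeR adjusted p = 0.356).

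The authors' deposited tables call 47 RNP-MaP sites in replicate 1 and 37 in replicate 2, of which 31 are at the same nucleotide. Independent lists of these lengths would share 6.06 of 287 nucleotides. Unchanged libraries simulated against the same control shared 4.30 sites on average and 11 at most, under the part of the calling rule that is known. Their lists were shorter, with 10.7 and 11.3 sites on average, so 4.30 is not the overlap that lists of 47 and 37 would give. In the authors' deposited tables, the shared sites fall on 13 A, 12 U, 4 G and 2 C. They form 16 runs, the longest from 53 to 58 with 6 sites, and the next from 296 to 302 with 5. The highest nucleotides of the runs were U21, U41, A56, U63, C75, G111, A126, A146, A155, U163, A169, U179, A187, C195, A238 and G300. In the authors' deposited table the ratio at G300 is 4.71 in replicate 1 and 4.93 in replicate 2. Of the 27 nucleotides above their base by edgeR, 23 are shared sites, 3 are sites in 1 replicate, and C108 is a site in neither. All 31 shared sites were higher than the control by uncentred edgeR, but 8, all adenosines, did not pass after centring on the base, among them A155 (centred log2 ratio 0.45, edgeR adjusted p = 0.168), A169 (0.19, 0.628), A187 (0.46, 0.0776) and A238 (0.27, 0.424). With the median of all nucleotides as centre, all 8 passed. U21 and G111, which did pass, had values of 0.57 and 0.57 (edgeR adjusted p = 0.00231 and 0.000224), but passed neither with DESeq2 (adjusted p = 0.249 and 0.108) nor with read depth as offset (adjusted p = 0.187 and 0.114). Only 10 shared sites had ratios of at least 1.5 times the authors' threshold in both replicates.

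Most enriched nucleotides lay in the SL1 and SL2 domains, which also held most of the measured nucleotides. Over the whole measured RNA, 27 of 287 nucleotides were above their base. SL1 held 14 of its 91 measured nucleotides above their base (8 by DESeq2) and 13 shared sites. SL2 held 8 of 90 (4 by DESeq2), near the share over the whole RNA, and 12 shared sites. SL3, a stem-loop known for binding hnRNP proteins, held 0 of 80 above by edgeR (3 at an unadjusted p under 0.05, and 0 by DESeq2) and 1 shared site. The linker held 2 of 20 (0 by DESeq2), and the measured 6 nucleotides of SL4 and tail held 3 (3 by DESeq2). No domain mean passed the exact circular-shift permutation test. SL4 and tail lay 0.43 ± 0.09 above the rest on the centred log2 scale (SD, n = 2 libraries; adjusted p = 0.218 by the exact circular-shift test), and SL3 lay at -0.17 ± 0.01 (adjusted p = 0.218). SL1 lay at 0.12 ± 0.01 (adjusted p = 0.499), and SL2 and the linker at -0.0014 and -0.0010 (adjusted p = 1 for both). The difference between SL1 and SL3 itself was not tested. With boundaries moved 5 nucleotides toward the 3' end, SL4 and tail held nucleotide 305 alone, without G300, and lay at -0.18.

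U40, U41 and U63, bulged uridines next to the GAUC motifs that HEXIM recognises, had centred log2 ratios of 0.59 (edgeR adjusted p = 0.000814), 0.72 (0.000288) and 1.23 (1.15e-09). The calls of U40 and U41 were lost with DESeq2 (adjusted p = 0.141 and 0.0983) and with edgeR and read depth as offset (adjusted p = 0.0564 and 0.114). U30, known as a nucleotide that crosslinks to HEXIM, had a value of -0.01 (edgeR adjusted p = 0.986). Of the GAUC motifs at 13, 42 and 64, the one at 13 lies outside the measured part. Among the 8 measured motif nucleotides, edgeR called 0 above and 0 below their base, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05, and DESeq2 called 0. Their values ran from -0.32 at A43 to 0.31 at A65, with -0.23 at G42, -0.08 at U44, -0.14 at C45, 0.03 at G64, 0.03 at U66 and 0.26 at C67. The value at A65 was 0.06 without SDA replicate 1 and 0.52 without SDA replicate 2. Without centring, A65 was higher than the control (edgeR adjusted p = 0.000849). Distal SL1, nucleotides 24 to 87, held 11 enriched nucleotides of 64, 11 adjusted over the list alone. Its mean lay 0.14 above the rest (exact circular-shift permutation test, adjusted p = 0.47), and that of the GAUC nucleotides lay at -0.10 (adjusted p = 0.47).

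Nucleotides predicted to be unpaired had slightly higher values than paired ones. The mean centred log2 ratio was 0.14 over 117 unpaired and 0.04 over 170 paired nucleotides, a difference of 0.10 ± 0.01 (SD, n = 2 libraries; exact circular-shift permutation test, p = 0.0244). Of the 27 enriched nucleotides, 15 were predicted unpaired and 12 paired, the latter including A56, U57, U63 and G300. U63, called bulged above, is paired in this prediction, so the predicted states can differ from the known structure of SL1. With pairing taken as a probability of at least 0.5, the difference was 0.16 (p = 0.00697 by the same exact test). On the scale of rate differences the call was lost (0.0959 mutations per 10000 reads, p = 0.819 by the same exact test), and the structure is a single prediction for the RNA without protein. Values were centred on base medians but compared as means, and the test does not hold the bases of each set fixed. An effect of unlike base composition was therefore not separated from pairing.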

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

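Of the tests in this part, the comparison with predicted pairing was written down before its result was seen. The tests on absolute rates and across libraries, on the nucleotides beside the primer, on centring and on a mixed template were chosen after the values they concern had been seen. No biological explanation was tested, since the design has only SDA and its control.

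Reads mapped off target, a signal outside the main measurement, made up a larger share in both SDA libraries than in the control. Their median share of read depth was 0.0813% in SDA replicate 1 and 0.0656% in SDA replicate 2, against 0.0596% in the control. With 1 control library the difference has no replicate check.

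The first pattern is the set of 27 nucleotides above the typical nucleotide of their base. If adducts were equally frequent everywhere, a low background alone could give high ratios, with no larger absolute increase. The median increase of the 27 exceeded that of other nucleotides of the same base by 5.78 mutations per 10000 reads, a value that their selection on the same libraries inflates to an unknown extent. Nucleotides were also selected in 1 SDA library by exact tests and measured in the other, against the upper 95% limit of the control. The median excess was still 1.78 (49 nucleotides selected in replicate 1) and 2.74 (37 in replicate 2). By this measure, 40 of the 49 and 34 of the 37 lay above the typical increase. Selection and measurement used the same control, whose spread beyond counting error was not measured. Within that limit, these values argue against equal adducts everywhere. Predicted pairing remains open: 55.6% of the 27 were unpaired, with an exact interval of 35.3% to 74.5%, against 39.2% of the others (Fisher's exact test, p = 0.105). Contact with protein and the exposure of a nucleotide to the reagent cannot be told apart for these 27, because no library without protein was analysed.

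The second pattern is the rise at nucleotides 299 to 302, near the end of the measured RNA. Nucleotides 303 to 305, nearer to the primer site, had a mean centred log2 ratio of -0.24, against 1.10 for 299 to 302. Because 299 to 302 were delimited by where the enriched nucleotides end, this contrast is largely fixed by the selection. It does not bear on an effect of the primer site, which stays open.

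The third pattern is the set of 12 nucleotides below the typical nucleotide of their base. Without centring, 2 of the 12 were lower than the control by edgeR. Yet 11 of the 12 had a lower rate than the control in both SDA libraries, and the ratios of the 12 ran from 0.777 to 1.00. The 12 were selected for low ratios in these libraries, which share 1 control, so the count of 11 is partly fixed by the selection. An effect of centring on the base and a fall below the control cannot be told apart for most of the 12. The count over both libraries was added as a condition after the count of 2 had been seen. A single minor template mixed into the control library would lower each by the same amount of rate. Their differences had a heterogeneity chi-square of 48.7 on 11 degrees of freedom against counting error (p = 1.06e-06). The SDA libraries themselves differed by more than counting error, with a chi-square of 1.80 per degree of freedom, so this value does not decide, and a mixed template stays open.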

How the results depend on the processing

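Of 115 comparisons with another setting, 66 concerned tested values: 56 kept direction and side of the threshold, 7 reversed, 2 became weaker and 1 stronger. Of 42 counts, 25 moved by no more than 1.5 times, 11 fell and 6 rose by more. Of 7 values without a test, 5 stayed within their spread or interval and 2 moved. Single named nucleotides kept their call or lack of one in 303 cases with both SDA libraries, and were weaker in 40 and stronger in 11. With a library left out, their centred ratios were taken as values with no test, and are not counted here. The causes of the changes listed here were not tested, except where stated. No paired analysis was possible because 1 control library served both SDA replicates. The control's own spread was not measured, and edgeR's small p-values rest on a spread shared between nucleotides: with read depth as offset the median total degrees of freedom fell from 287 to 3.53, and fewer nucleotides passed.

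Nucleotides higher than the control numbered 85, and 27 with DESeq2 and 20 with read depth as offset, all among the 85. Those lower numbered 2, and 0 with DESeq2, 0 with read depth, 1 without 10 nucleotides at each end (C304 is then not tested), and 4 to 9 with 1 SDA library left out, of which the 9 held both and the 4 only G151. Nucleotides above their base numbered 27, and 15 with DESeq2, 9 with read depth, 85 with no centring, and 37 to 49 with 1 SDA library left out, where exact tests ignore the spread between libraries; each of these leave-outs kept all 27. Those below numbered 12, and 2 with DESeq2, 0 with read depth, 2 with no centring, and 21 to 25 with 1 SDA library left out, which held all 12 without replicate 2 and 9 of the 12 without replicate 1.

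The ratio of median rates, 1.36, was 1.14 when taken from mean rates. As a difference of rates per 10000 reads, the base preference became -0.0564 for A and 0.0629 for G (both turned), and 1.71 for U (now past the threshold); agreement between SDA libraries fell to r = 0.771; and unpaired minus paired was 0.0959, no longer past it. The value for C lay between -0.11 and -0.10 with 1 SDA library left out, past the threshold only with replicate 1. Shared authors' sites fell from 31 to 10 under the stricter ratio. Domain values that changed sign never passed: the linker with boundaries moved toward the 3' end (0.17), with the median of all nucleotides as centre (0.0695) and without an SDA library (-0.0032 to 0.0115), SL2 without an SDA library (-0.0070 to 0.0076), and SL4 and tail with boundaries moved toward the 3' end (-0.18). With boundaries moved that way, SL4 and tail held nucleotide 305 alone, and G300, A301 and G302 fell in the linker.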

Other observations

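The test in this part was chosen after the positions had been seen. The 27 enriched nucleotides included 12 uridines, 5 adenosines, 5 cytidines and 5 guanosines, while 31 of the 85 nucleotides higher without centring were adenosines. Centring subtracted a larger median log2 ratio for A (0.487) than for U (0.155), so this shift between bases is set at least in part by the centring. The 27 held 10 pairs of adjacent nucleotides. The same number per base placed at random along the 287 nucleotides gave 2.34 such pairs on average and 8 at most (permutation test, p = 1e-04, the smallest that 10000 permutations can give). The positions that prompted this test are also those it was run on, so the clustering is a hypothesis. A candidate explanation for the 10 pairs is that neighbouring nucleotides share a contact, but an adduct may also cause mutations next to the crosslinked nucleotide, and the count of pairs does not separate these.

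U191 had a rate of 0.832% in SDA replicate 1, 1.05% in replicate 2 and 1.08% in the control. C295 had 0.563%, 0.705% and 0.518%. The reference gene table lists 293 RN7SK pseudogenes, and whether reads from them were counted is not given in the sources used here.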
